A study of Mus musculus with 3 samples.

How the data were processed

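Accutase-dissociated cells from 34 pooled wild-type mouse otocysts of the embryonic stage E10.5 were divided into 3 samples for CUT&Tag with an antibody against CHD7, an antibody against SOX2 or no primary antibody, with 1 library each, per the labels' protocols. Paired-end reads were sequenced on an Illumina instrument, per the labels. Bowtie2, deepTools and SEACR and the mouse build mm10 are named, per the submitters' processing notes; their versions, the peak calling settings, the use of the control library and the handling of duplicates are not given in the sources used here. The deposited values of each peak are its coverage signal summed over its bases and its highest coverage signal, as the authors' SEACR-style lists give them, with 1 list per library. How that signal was scaled is not given in the sources used here. Within each list every maximum signal was a whole multiple of a step (within 0.02 of a step), 0.0911 for CHD7 and 0.587 for SOX2. The smallest total signal was 433 for CHD7 and 733 for SOX2. Counted in steps over a bin of 50 bases these are 95 and 25, so the SOX2 list reached lower in steps. Signal was therefore used only to rank, describe or filter peaks of the same list. Read depth cannot be read from the lists, and the precision given is that of the number of peaks. Peak borders follow bins of 50 bases, and coordinates are printed counting from 1.

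A CHD7 peak was shared when it had at least 1 base in common with a SOX2 peak. The share was compared with 1000 random placements of the CHD7 peaks, keeping widths and chromosomes and avoiding stretches of over 500 kb without a peak or gene, which stood for assembly gaps. Intervals of shares are exact binomial (Clopper-Pearson) at 95%. Shared and unshared peaks were compared by the ratio of median total signal, with 100000 resamples. Peaks were joined into clusters at distances of up to 10 kb.

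Gene positions came from a RefSeq gene table of the assembly GRCm38.p6, the build also called mm10, with 21887 protein-coding genes outside the mitochondrial genome. No strand and no genome sequence were used here. The planned window of 1 kb around transcription start sites was therefore replaced by 1 kb around either end of a gene, which also takes in the ends of transcripts, and exons, introns and untranslated regions were not told apart. Gene ends were the outer borders of each gene, so start sites inside a gene were missed. A gene without an end peak can still have peaks at such a site. The planned matching of random gene lists on CpG content and the planned test of SOX and other motifs were not run. A peak was put in the first class that applied: gene end, gene body, between genes.

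For 24 gene lists, the number of members with a peak at a gene end was compared with 10000 random lists of protein-coding genes matched on decile of gene length. The number of peaks in the genes extended by 50 kb on each side was compared in the same way, matched on locus length. Peaks were summed over the members of a list, so a peak in the loci of neighbouring members was counted more than once. Permutation tests of lists were one-sided for higher counts, with Benjamini-Hochberg adjustment over 72 tests per measure (24 lists for CHD7, SOX2 and both), and a list was called at an adjusted p under 0.05. The lists covered otic genes (otocyst regulators, prosensory, semicircular canal, neuroblast, and hearing loss and CHARGE-related genes), the SOX family, chromatin remodelers, Notch, FGF, BMP, WNT, SHH and retinoic acid pathways, cell cycle and ribosomal protein genes, markers of other cell types, and olfactory and vomeronasal receptors. Lists, tests and most alternatives were fixed before the data were examined.

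Genes were named by a fixed rule. Chd7 and Sox2 were always named. From each otic, family or pathway list the rule took up to 6 genes with an end peak in both lists, ranked by the worse of their ranks of summed end signal, and up to 2 genes with neither; from other lists it took up to 3 genes with both. The 10 strongest peaks and shared pairs were taken by total signal. The text names a subset of these, and Hox and histone genes named in the closing section were chosen after their values were seen.

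Alternatives were stricter peak sets, other rules for a shared peak, other gene-end windows and locus sizes, peaks away from gene ends, unmatched lists, a smaller joining distance, and, added after seeing the data, peaks shifted by 10 to 50 kb and random lists without olfactory and vomeronasal receptors. The methods were tested on simulated data made from the CHD7 list. With 30% planted sharing above random placement 30.0% was recovered over 33035 peaks, and with none -0.093%. Of 200 random lists of 25 genes 2.5% had p under 0.05 at gene ends and 4% in loci, against 94.5% and 96% of lists with planted excess, over 21887 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.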

Results

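The otocyst is the epithelial vesicle from which the inner ear develops. CUT&Tag, in which an antibody directs the Tn5 transposase to DNA near a bound protein, was applied to wild-type mouse otocysts dissected at the embryonic stage E10.5. Cells of 34 pooled otocysts were divided into 3 samples. The first received an antibody against CHD7, an ATP-dependent chromatin remodeler mutated in CHARGE syndrome, and the second an antibody against SOX2, an HMG-box transcription factor needed for the sensory regions of the inner ear. The third received no primary antibody and is not analysed here. Below, a protein is said to be at a place where its list has a peak, which does not by itself show binding. The CHD7 list held 33035 peaks covering 33.5 Mb, with a median width of 950 bases and an interquartile range of 650 to 1250. The SOX2 list held 155548 peaks covering 107 Mb, with a median width of 650 bases and an interquartile range of 500 to 800. Read depth is unknown. Each peak carries the authors' total and maximum coverage signal, used here only to rank and describe peaks within a list. Signal rose in equal steps, and the median peak reached a maximum of 20 steps in the CHD7 list and 6 steps in the SOX2 list. With 1 library per antibody no result has a replicate check, and p-values and intervals describe counting or random placement within these libraries. PCR reads without molecular identifiers are not independent molecules, so the intervals cover counting error only.

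The first comparison asked how often both proteins were detected at the same place. Most CHD7 peaks lay on a SOX2 peak: 21586 of 33035 shared at least 1 base with one, or 65.3% (exact 95% binomial interval 64.8% to 65.9%). The reverse share was smaller, with 22909 of 155548 SOX2 peaks, or 14.7% (14.6% to 14.9%), on a CHD7 peak. CHD7 peaks at the ends of protein-coding genes overlapped SOX2 most often, at 85.7% (84.8% to 86.5%), against 61.7% within gene bodies and 60.3% between genes. For SOX2 peaks the same places gave 35.0%, 10.8% and 13.8%. When the CHD7 peaks were placed at random on their own chromosomes 1000 times, 9.94% overlapped a SOX2 peak on average and 10.46% at most. The observed share was 6.58 times the random mean (one-sided permutation p = 0.001, the smallest these placements can give). The share depended on which peaks were counted: among the 10000 strongest peaks of each list 46.4% of CHD7 peaks overlapped SOX2, 33.1 times the random mean, and 19.8% of all CHD7 peaks did so when the maximum-signal regions themselves had to share a base. The gap between the 2 directions followed list length: 46.9% of the 10000 strongest SOX2 peaks overlapped CHD7, and with the SOX2 list limited to the length of the CHD7 list the shares were 40.4% and 40.6%.

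Overlap was highest among the strongest peaks. Of the 10% of CHD7 peaks with the highest total signal 89.9% overlapped a SOX2 peak (exact 95% interval 88.8% to 90.9%), and of the weakest 10% 45.5% did (43.8% to 47.2%). The same CHD7 peaks moved by 10 to 50 kb overlapped SOX2 at 16.6% and 10.3%. SOX2 peaks ran from 5.18% (4.83% to 5.54%) in the weakest 10% to 58.6% (57.8% to 59.3%) in the strongest 10%, where moved peaks gave 2.04% and 4.61%. Shared CHD7 peaks had a median total signal of 738 against 560.2 in unshared ones, a ratio of 1.32. Shared SOX2 peaks had 1671 against 938, a ratio of 1.78. Both ratios passed a permutation test with 100000 resamples (p = 1e-05, the smallest it can give). Shared peaks were also wider, with medians of 1000 against 800 bases for CHD7 and 750 against 600 for SOX2, and the ratios of total signal per base were 1.06 and 1.34.

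**Figure D1:**
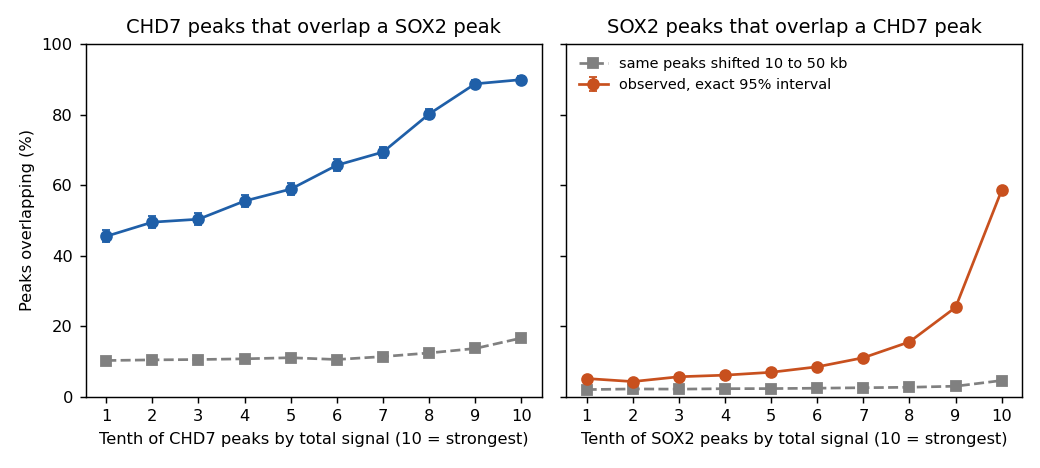
Share of peaks (%) overlapping the other list, by group of 10% of the peaks ordered by total signal, from 1 (weakest) to 10 (strongest), for CHD7 peaks (left) and SOX2 peaks (right). Circles are observed shares with exact 95% intervals and grey squares the mean of the same peaks shifted by 10 to 50 kb; observed shares reach 89.9% and 58.6% at the right edge.

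CHD7 peaks gathered at gene ends more than SOX2 peaks did when the full lists were compared. Within 1 kb of either end of a protein-coding gene lay 6049 CHD7 peaks, or 18.3% (exact 95% interval 17.9% to 18.7%), and 15303 SOX2 peaks, or 9.84% (9.69% to 9.99%). Both exceeded random placement, by 4.13 times for CHD7 and 2.43 times for SOX2 (one-sided permutation p = 0.001 for each, the smallest possible). Another 29.6% of CHD7 peaks and 38.3% of SOX2 peaks lay within gene bodies, and 52.1% and 51.9% lay between genes. At equal length the order of the 2 lists turned: among the 10000 strongest peaks 24.1% of CHD7 peaks (23.2% to 24.9%) and 31.6% of SOX2 peaks (30.7% to 32.5%) were at gene ends.

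Most genes with a CHD7 peak at an end also had a SOX2 peak at an end. Of 21887 protein-coding genes 6742 (30.8%) had a CHD7 peak at an end, 13069 (59.7%) a SOX2 peak, and 6192 both, which is 91.8% of the CHD7 genes. Independent lists of these sizes would share 4026 genes, so the observed number was 1.54 times that. CHD7 without SOX2 was found at 550 genes and neither protein at 8268. Genes are not replicates and no p-value is given. The numbers of genes fell with stricter peak sets, to 2911 for CHD7, 3702 for SOX2 and 1983 for both with the 10000 strongest peaks of each list. There 68.1% of the CHD7 genes also had SOX2, 4.03 times the number for independent lists, and with the stronger 50% of peaks these values were 92.1% and 1.91 times.

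Peaks of both lists lay at an end of Sox2 itself. Sox2 (chromosome 3, 34649995 to 34652461, mm10) had CHD7 peaks at 34648751 to 34649950 (total signal 478) and at 34650151 to 34651450 (total signal 993), both at its lower-coordinate end. The first was close to the lowest total signal in the CHD7 list, 433. SOX2 peaks at 34648701 to 34650600 (total signal 3138) and at 34650751 to 34651350 (total signal 938) overlapped them. Within 50 kb of the gene there were 7 CHD7 and 13 SOX2 peaks, and 4 of the CHD7 peaks were shared. Chd7 (chromosome 4, 8690402 to 8868449) had no CHD7 peak at either end and 1 SOX2 peak at its higher-coordinate end, at 8869101 to 8869950 (total signal 1056). Inside the Chd7 gene body peaks of both lists overlapped at 2 places. A CHD7 peak at 8730701 to 8731550 (total signal 656) overlapped the strongest SOX2 peak of the gene, at 8730551 to 8731350 (total signal 5014), and a CHD7 peak at 8780051 to 8780600 (total signal 1293) overlapped a SOX2 peak at 8780001 to 8780550 (total signal 1202). Whether these places are exonic or intronic was not determined. The Chd7 gene with 50 kb on each side held 7 CHD7 and 23 SOX2 peaks.

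**Figure D2:**
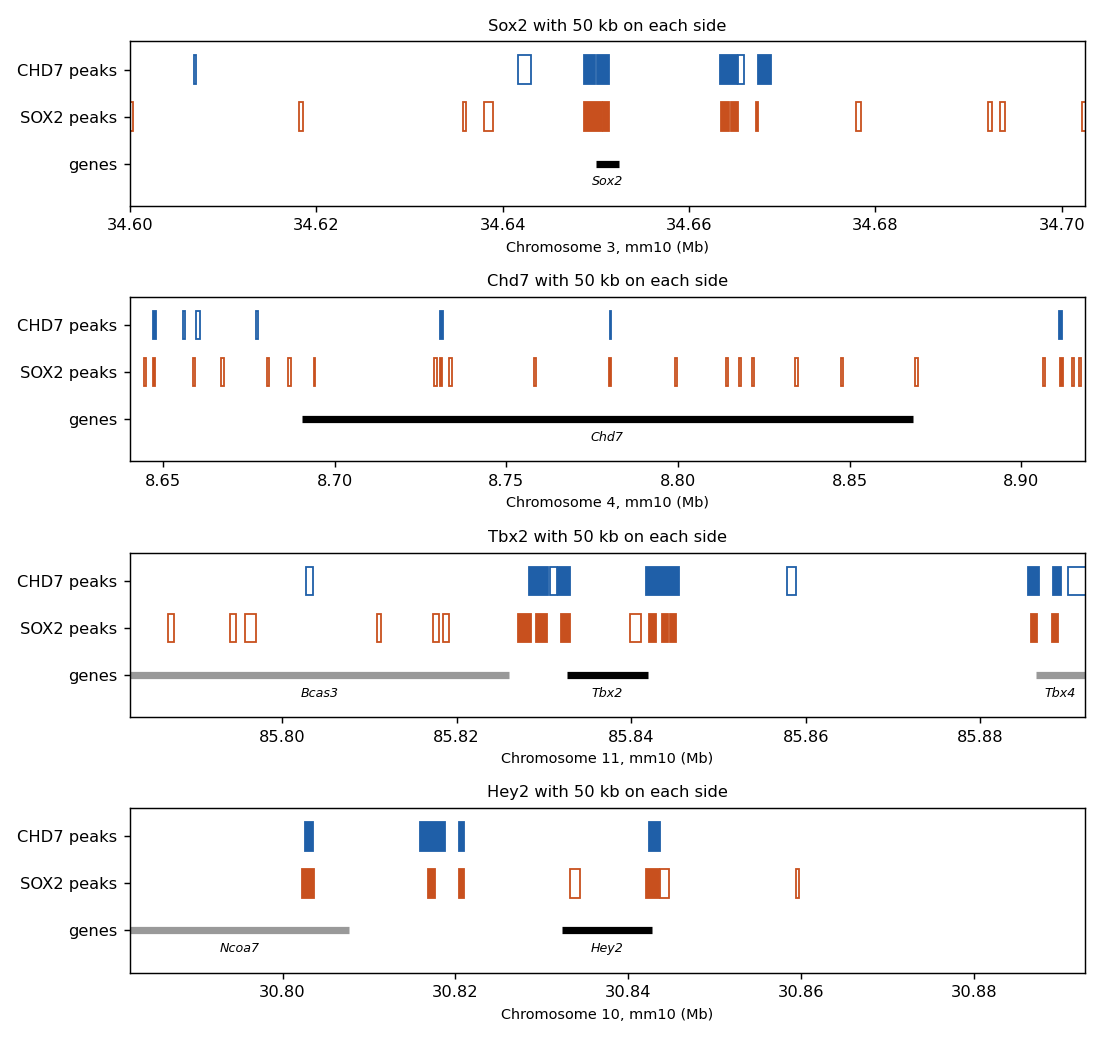
CHD7 peaks (blue) and SOX2 peaks (orange) around Sox2, Chd7, Tbx2 and Hey2 with 50 kb on each side, against position (Mb, mm10); filled boxes overlap a peak of the other list and bars are genes. Filled boxes lie at an end of Sox2, Tbx2 and Hey2, and no filled box lies at an end of Chd7.

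Regulators of the otic placode and otocyst carried CHD7 at their ends more often than other genes. A CHD7 peak was present at 22 of 32, against 9.54 on average in random lists matched on gene length (adjusted permutation p = 0.0024), a SOX2 peak at 27 of 32 against 19.2 (adjusted p = 0.01215), and both at 20. Examples with both were the T-box gene Tbx2 (summed end signal 3411 for CHD7 and 7008 for SOX2), the homeobox gene Gbx2 (2227 and 5014), Msx1 (1271 and 4868) and Id3 (3138 and 3988). Pax2 and Pax8, paired-box genes of the otic placode, had neither protein at an end, where start sites inside the gene are not covered. Within Pax2, however, CHD7 and SOX2 peaks overlapped at 44749851 to 44751050 and at 44755301 to 44757000 on chromosome 19 (CHD7 coordinates). Of the sensory and prosensory genes 14 of 24 had CHD7 (random mean 7.49, adjusted permutation p = 0.02268) and 21 had SOX2 (random mean 14.8, adjusted p = 0.02236). They included Myo6, which encodes a hair cell myosin (2072 and 8328), Sox21 (1945 and 9031), Isl1 (2195 and 4662), and the Notch ligand Jag1 (1061 and 6392). The hair cell transcription factor genes Pou4f3 and Gfi1 had neither.

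Semicircular canal genes passed for SOX2, with 23 of 24 carrying a SOX2 peak (random mean 15.4, adjusted permutation p = 0.0024), among them Lrig1, Has2, Hmx3 and Lrig3. CHD7 was at 12 of these 24 (random mean 8.03), which did not pass (adjusted permutation p = 0.1691). Hmx2, the neighbour of Hmx3, had neither. The neuroblast and otic neurogenesis genes did not pass: CHD7 was at 7 of 22 (adjusted permutation p = 0.8533) and SOX2 at 15 of 22 (adjusted p = 0.7431). Neurog1, the proneural gene of the otic ganglion, had both peaks, with an end signal of 2287 for SOX2 and of 455 for CHD7, close to the lowest total signal in the CHD7 list, 433. Of the hearing loss and CHARGE-related genes 10 of 30 had CHD7 (adjusted permutation p = 0.8342) and 20 had SOX2 (adjusted p = 0.747). Kdm6a, Pax3, Grhl2 and Sall1 were among those with both. With gene ends taken as 500 bases the SOX2 calls of the otic regulators and of the semicircular canal genes were lost (adjusted permutation p = 0.1205 for each), and with the stronger 50% of peaks the CHD7 call of the prosensory genes was lost (adjusted p = 0.08862).

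**Figure D3:**
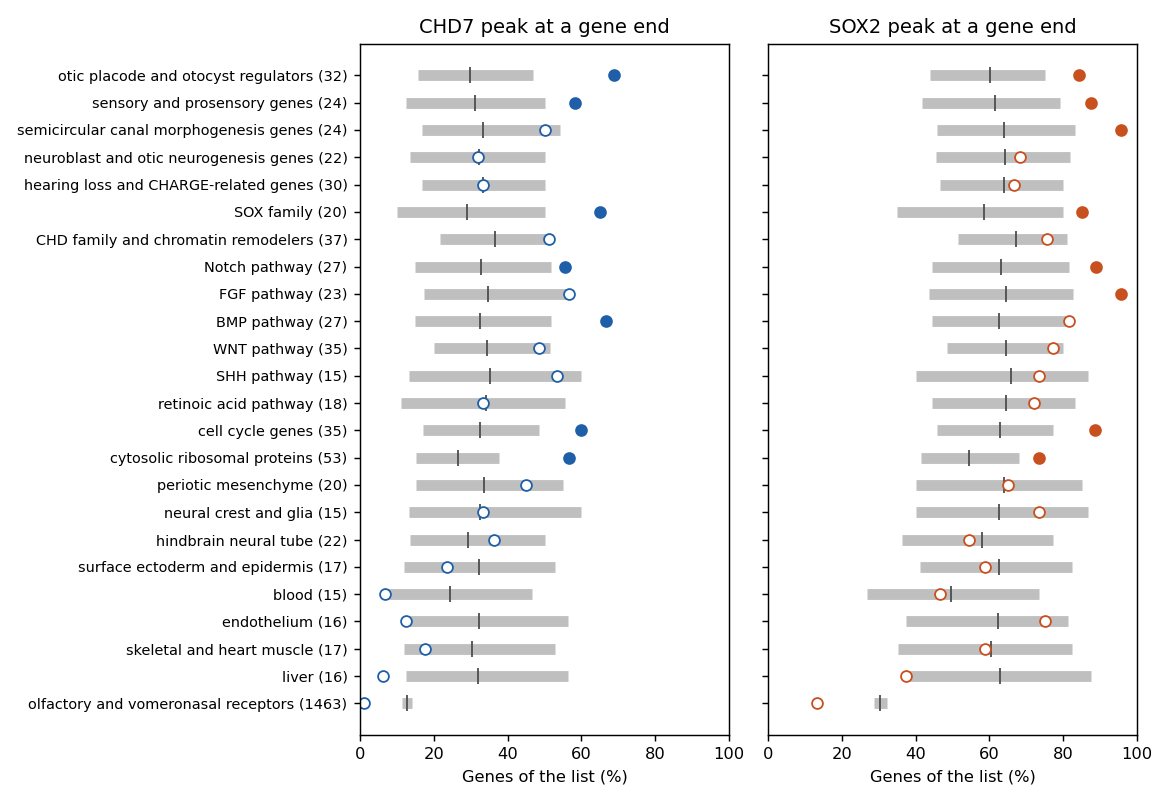
Genes of each list (%; list size in parentheses) with a CHD7 peak (left) or a SOX2 peak (right) within 1 kb of a gene end. Grey bars span 95% of 10000 random lists matched on gene length, ticks mark their mean, and filled circles have a Benjamini-Hochberg adjusted permutation p under 0.05; the otic regulators lie above the bar in both panels and the olfactory and vomeronasal receptors below it.

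Among signalling pathways, BMP genes passed for CHD7, FGF genes for SOX2 and Notch genes for both. CHD7 was at 18 of 27 BMP pathway genes (random mean 8.78, adjusted permutation p = 0.0024), including the antagonist Nog and the target genes Id1, Id2 and Id3; SOX2 was at 22 (adjusted p = 0.08208), and the receptor gene Bmpr1a had neither. SOX2 was at 22 of 23 FGF pathway genes (random mean 14.8, adjusted permutation p = 0.00576), and CHD7 at 13 (adjusted p = 0.0786). The FGF feedback gene Dusp6 had end signals of 2669 for CHD7 and 9031 for SOX2, and the ETS factor genes Etv1 and Etv5 also had both. Notch pathway genes passed for CHD7 with 15 of 27 (adjusted permutation p = 0.03663) and for SOX2 with 24 of 27 (adjusted p = 0.01652). The Notch effector gene Hey2 had a summed SOX2 end signal of 12989.9 from 3 peaks, and Rbpj, the DNA-binding partner of Notch, had no end peak. Counted as genes with both proteins, BMP (16 of 27, adjusted permutation p = 0.01131), Notch (15 of 27, adjusted p = 0.0168) and FGF genes (13 of 23, adjusted p = 0.03663) passed, in 5, 3 and 2 of 5 alternatives respectively. All 15 Notch genes and all 13 FGF genes with CHD7 also had SOX2, so the test for both largely repeats the CHD7 test. A gene also counted as having both when its peaks did not overlap or lay at different ends. Whether CHD7 and SOX2 differed in their preference for a pathway was not tested. WNT genes (17 of 35 with CHD7, 27 with SOX2), SHH genes (8 and 11 of 15) and retinoic acid genes (6 and 13 of 18) passed for neither protein, with adjusted permutation p from 0.1497 to 0.8533. The Notch calls were lost with gene ends of 500 bases (adjusted permutation p = 0.2054 for both proteins), and the CHD7 call also with the stronger 50% of peaks (adjusted p = 0.09307). WNT genes passed for CHD7 with the stronger 50% of peaks (adjusted permutation p = 0.03564), FGF genes for CHD7 without matching on length (adjusted p = 0.0313), and the BMP genes passed for SOX2 in 3 of 5 alternatives (lowest adjusted p = 0.02965).

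Genes of the SOX family passed for both proteins, with CHD7 at 13 of 20 (random mean 5.81, adjusted permutation p = 0.00576) and SOX2 at 17 (random mean 11.7, adjusted p = 0.03394). Sox8 (end signals 2796 for CHD7 and 9501 for SOX2), Sox21, Sox17, Sox9, Sox2 and Sox11 had both, and Sox7 and Sox30 had neither. Chromatin remodelers did not pass: CHD7 was at 19 of 37 (adjusted permutation p = 0.132) and SOX2 at 28 (adjusted p = 0.3767), with Smarca4, Ep400 and Ezh2 among those with both and Chd2 among those with neither. The SOX2 call of the SOX family was lost with gene ends of 2 kb (adjusted permutation p = 0.1346), and the chromatin remodelers passed for CHD7 in 3 of 5 alternatives (lowest adjusted p = 0.01886).

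Genes active in most cells carried both proteins as well. CHD7 was at 21 of 35 cell cycle genes (random mean 11.3, adjusted permutation p = 0.005891) and at 30 of 53 cytosolic ribosomal protein genes (random mean 14.1, adjusted p = 0.0024). SOX2 was at 31 of 35 (adjusted permutation p = 0.00576) and 39 of 53 (adjusted p = 0.01215). The SOX2 call of the ribosomal protein genes was lost without matching on length (adjusted permutation p = 0.06008). Mcm4, Cdk4, Rps29 and Rpl7 were examples with both. No marker list of another cell type passed at gene ends. CHD7 and SOX2 were at 9 and 13 of 20 periotic mesenchyme genes, 5 and 11 of 15 neural crest and glia genes, 8 and 12 of 22 hindbrain genes, and 4 and 10 of 17 surface ectoderm genes. They were at 1 and 7 of 15 blood genes, 2 and 12 of 16 endothelial genes, 3 and 10 of 17 muscle genes, and 1 and 6 of 16 liver genes. Olfactory and vomeronasal receptor genes, a large family silent in most tissues, carried fewer peaks than random lists: 15 of 1463 had CHD7 against 186 and 193 had SOX2 against 445 (adjusted permutation p for lower counts = 0.0024 for each). The lists share some members, such as Sox2, Jag1 and Spry2, so their results are not independent.

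Around the genes, otic regulators again held more CHD7 peaks than random lists. With 50 kb added on each side their loci held 139 CHD7 peaks against 76.9 in random lists matched on locus length (adjusted permutation p = 0.0036). They held 102 CHD7 peaks shared with SOX2 against 55.7 (adjusted permutation p = 0.0036), and 416 SOX2 peaks against 353 (adjusted p = 0.1662). The CHD7 result passed in all 5 alternatives run for it, and the shared one was lost with 100 kb on each side (adjusted permutation p = 0.05184). Cell cycle genes (135 against 86.4, adjusted permutation p = 0.009), Notch genes (102 against 70.1), SOX genes (77 against 48.7) and ribosomal protein genes (158 against 115) also had more CHD7 peaks, the last 3 each with an adjusted p of 0.04451. Notch genes were the single list called for SOX2 peaks at 50 kb, with 450 against 327 (adjusted permutation p = 0.04451). Other lists, such as the otic regulators, also held more SOX2 peaks than their random mean without passing. Shared peaks were also more frequent at cell cycle (100 against 62.6, adjusted permutation p = 0.009), Notch (76 against 49.9), ribosomal protein (121 against 84.5) and SHH genes (51 against 30.1), the last 3 each with an adjusted p of 0.04451. The shared calls of SHH and ribosomal protein genes were lost in all 5 alternatives, the Notch calls for SOX2 and for shared peaks and the CHD7 calls of SOX and ribosomal protein genes in 4 of 5, the CHD7 call of Notch genes in 3 and both calls of cell cycle genes in 2. Some lists passed only with 5 kb on each side: hindbrain genes for CHD7 (31 peaks against 13.1, adjusted permutation p = 0.00432), sensory and prosensory genes for CHD7 (40 against 21.2, adjusted p = 0.04834) and shared peaks (33 against 15.3, adjusted p = 0.0168), and SOX genes for SOX2 (157 against 69.4, adjusted p = 0.0126) and shared peaks (37 against 11.6, adjusted p = 0.00432). Sensory and prosensory genes passed for SOX2 with 5 kb (179 against 95.5, adjusted permutation p = 0.0186) and with the stronger 50% of peaks (233 against 155, adjusted p = 0.0288). All these locus counts were summed over genes, so peaks in overlapping loci of neighbouring genes counted more than once. The hindbrain list holds neighbouring Hox genes, and the otic regulators hold neighbours such as Hmx2 and Hmx3. Random lists were drawn without regard to neighbours, so repeated counting can add to an excess and lower its p. How much it adds was not tested.

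The strongest peaks mostly lay outside the genes above. The highest total signal in the CHD7 list, 143270, belonged to a peak of 38350 bases at 123537301 to 123575650 on chromosome 8, outside the gene and 0.644 kb from an end of Gas8. A peak at 47650301 to 47687050 on chromosome 6, over predicted genes such as Gm40365, ranked 3 for CHD7, and the SOX2 peak at 47652651 to 47687050 ranked 1 in its list. A peak at 39842951 to 39848850 on chromosome 17, over the ribosomal RNA pseudogene Rn18s-rs5, had the same borders in both lists. Some of the strongest CHD7 peaks had no SOX2 partner, inside Mepe (chromosome 5, 104330451 to 104332450), Actr3b (chromosome 5, 25815701 to 25818800) and Asic4 (chromosome 1, 75460501 to 75462900). Their maximum signals were 141, 163.2 and 140.8 in that order, against a list median of 1.82. Whether repeats or mappability produced the strongest peaks of either list was not tested. Of the 100 strongest peaks 37% in the CHD7 list and 28% in the SOX2 list were wider than 5 kb or on unplaced sequences. Joined at distances of up to 10 kb, peaks formed 152 clusters of 5 or more for CHD7 and 5961 for SOX2, and at up to 5 kb 78 and 2501. The CHD7 cluster with the most peaks held 31, at 114492851 to 114637750 on chromosome 6, 5.38 kb from Atg7, and the next held 17, at 23517251 to 23586150 on chromosome 13, over a run of 15 histone genes. The largest SOX2 cluster held 180 peaks at 7242201 to 7668000 on chromosome 14, over predicted genes such as Gm3727.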

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

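The comparisons with shifted peaks and with random lists lacking olfactory and vomeronasal receptors were chosen after the results were seen. Of 82 recomputed values, 53 stayed on the same side of their threshold or within the allowed range and 29 moved. A change of direction could be recorded only for the CHD7 share, the shares at gene ends and the signal ratios, and 0 of these changed direction. For gene lists the value was the number of lists called, so single calls could be lost within the allowed range. The CHD7 share on SOX2 peaks stayed above random or shifted placement in all 11 alternatives, from 4.32 to 33.1 times, and the excess of both lists at gene ends and the signal ratios of shared peaks kept their direction and significance in every alternative run for them. The share of SOX2 peaks on CHD7 peaks became 15.3% with the stronger 50% of each list, 46.9% with the 10000 strongest peaks and 40.6% with the SOX2 list limited to the length of the CHD7 list. It became 14.0% with 50% of the narrower peak shared, 9.87% with 50% of each peak and 4.21% with maximum-signal regions. Genes with an end peak numbered 4237 for CHD7 and 3901 for both with the stronger 50%, and 2911, 3702 and 1983 for CHD7, SOX2 and both with the 10000 strongest peaks; fewer peaks entered by construction. Lists called at gene ends numbered 5 for SOX2 with ends of 500 bases and 5 for both with the stronger 50%. Lists called by locus numbered, for CHD7, SOX2 and both, 1, 0 and 0 with 100 kb on each side, 1, 0 and 1 away from gene ends, 3, 2 and 2 with the stronger 50%, and 2, 0 and 2 with random lists lacking receptor genes; with 5 kb on each side SOX2 had 2. Clusters of 5 or more joined at 5 kb numbered 78 for CHD7, 2501 for SOX2 and 39 for shared CHD7 peaks. Except where fewer peaks entered, the cause was not tested. Alternatives that need transcription start sites, CpG content or motifs were not run, and random placement of SOX2 peaks within classes gave no value. No paired analysis was possible because each antibody had 1 library. Without the read depth, absence of a peak means only that none was listed at this threshold.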

Other observations

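The tests on Hox, histone and tRNA genes, on shifted peaks, on otic against housekeeping and adjacent tissue lists, on chromosome X and on the weakest SOX2 peaks were added after the peak lists had been examined. Hox genes, which pattern the body axis, and histone genes were picked after their values had been seen, so no p-value is given for them. CHD7 was at an end of 20 of 39 Hox genes (mean of random lists matched on gene length 11.4) and SOX2 at 13 (random mean 23.0). CHD7 without SOX2 occurred at 11 Hox genes against 1.03 in random lists, among them Hoxa10, Hoxa13, Hoxd9 and Hoxd13. Neighbouring Hox genes can share a peak, and these counts rest on 20 CHD7 and 13 SOX2 peaks.

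Most histone genes had peaks of both proteins at an end. CHD7 was at 61 of 67 histone genes (random mean 6.73), SOX2 at 61 (random mean 17.5) and both at 58 (random mean 6.13), from 43 CHD7 and 62 SOX2 peaks. These random lists were matched on gene length and so hold short genes. Of all protein-coding genes 30.8% had CHD7 and 59.7% SOX2 at an end, against 91.0% of histone genes for each protein. Transfer RNA genes were also often marked, with CHD7 at an end of 206 of 408 (50.5%, exact 95% interval 45.5% to 55.4%) and SOX2 at 63.7%. Long noncoding RNA genes had 13.1% and 40.2%, and pseudogenes 2.78% and 19.4%. Near-identical copies of histone and tRNA genes can share reads, so the gene-by-gene counts of these families are uncertain.

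CHD7 peaks fell on SOX2 peaks 5.55 times as often as the same peaks shifted by 10 to 50 kb, which argues against peak density over regions of that scale as the whole cause. Away from gene ends the ratio was 5.58, and without the strongest 10% of each list it was 4.32. Neither shared gene ends nor regions of very high signal therefore account for the whole excess. Mappability and repeats at the peak positions themselves stay open, because a shift moves the peaks to other sequence. The weakest 10% of SOX2 peaks overlapped CHD7 peaks 2.53 times as often as shifted ones (5.18% against 2.04%). For the next 10% the ratio was 1.94 (4.31% against 2.22%). These ratios argue against all of these weak peaks being placed at random. Most of the weak peaks overlapped no CHD7 peak, and the ratios cannot tell whether those are background. Open chromatin tagmented without a specific antibody stays open as an explanation for all of this, because 0 peak lists of the library without primary antibody were analysed. No biological explanation was tested.

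SOX2 peaks were sparse on chromosome X, at 0.435 times the autosomal density per Mb, and CHD7 peaks were at 0.729 times. The lowest single autosome was at 0.872 for SOX2 and 0.878 for CHD7. A lower X copy number in a pool of embryos, acting through a fixed signal threshold, is a candidate explanation: with autosomal signal multiplied by 0.5, a share of 0.210 of SOX2 and 0.292 of CHD7 peaks would stay above the lowest listed signal, and with 0.75 shares of 0.525 and 0.625. Read this way, the X ratio of SOX2 would need a factor of 0.694 (0.658 to 0.735 over the spread of single autosomes) and that of CHD7 a factor of 0.819 (0.772 to 0.896), so no single factor served both lists although the libraries came from the same pool, and the explanation stays open because the threshold model is a simplification. The sexes of the embryos are not given in the sources used here, and X inactivation and mappability were not tested. Both lists held peaks on chromosome Y, 217 for CHD7 and 1221 for SOX2. Whether these came from male embryos was not tested.

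Otic genes carried CHD7 at an end in 49.5% of 103 genes, against 21.5% of 130 marker genes of other cell types, a difference of 28.0 percentage points (one-sided permutation p = 1e-05, the smallest possible; adjusted p = 4e-05). For SOX2 the shares were 77.7% and 56.2%, a difference of 21.5 points (p = 0.00047, adjusted permutation p = 0.00094). Unlike the list tests above, the comparisons of groups in this paragraph were not matched on gene length, nor on CpG content. Genes present in both groups were left out. Genes are not replicates, and the p-values describe relabelling of genes only. Part of the CHD7 difference rests on blood, endothelium, muscle and liver markers, of which 6.25% to 17.6% had CHD7. Against mesenchyme, neural crest, hindbrain and surface ectoderm alone, a grouping made after the values were seen, the differences were 17.7 points for CHD7 and 20.1 for SOX2. The SOX2 difference was thus little changed. The neuroblast and hearing loss lists lay within the range of these 4 lists, with 31.8% and 33.3% against 23.5% to 45% for CHD7. For SOX2 they had 68.2% and 66.7% against 54.5% to 73.3%. Against cell cycle and ribosomal protein genes the difference was -7.01 points for CHD7 (one-sided permutation p = 0.87) and -0.411 points for SOX2 (p = 0.6). The otic regulators, the otic list with the highest CHD7 share, had 68.8%, against 60% of cell cycle and 56.6% of ribosomal protein genes. For SOX2 the otic regulators had 84.4%, against 88.6% and 73.6%. These differences between single lists were not tested. Whether CHD7 at gene ends follows gene activity stays open, because no expression data were analysed here.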
